A study of Danio rerio with 8 samples.

How the data were processed

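The series holds reduced representation bisulfite sequencing of zebrafish Müller glia, the radial glia of the retina, sorted from dissociated retinas by GFP fluorescence, with a fluorescent morpholino tag as a further gate where a morpholino was given. In this assay the enzyme MspI cuts DNA at CCGG whether or not the inner CpG is methylated, fragments with inserts of 40 to 220 bp are kept, and bisulfite converts unmethylated cytosines so that they are read as T. The 8 libraries form 4 groups of 2: uninjured glia and, after needle injury of the retina, glia at 4 days post injury (dpi), at 2 dpi with a control morpholino and at 2 dpi with a morpholino pair against apobec2a,2b. A morpholino is an antisense oligomer that blocks splicing or translation of its target RNA. Knockdown of the target genes was not measured in these data.

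The deposited files list every covered cytosine in 3 contexts (CpG, CHG and CHH, where H is any base but G), with its chromosome, base, strand, coverage as a count of reads and the percent of reads read as C and as T, per the file headers. CASAVA 1.8.2, Trim Galore 0.2.1, Bismark 0.7.3 and methylKit 0.5.4 and the genome build Zv9 are named in the submitters' processing notes. Their settings are not given in the sources used here. The deposited counts are neither normalized nor pooled over libraries, and multiplying coverage by the percent gave whole reads for 100% of the cytosines in each library. The lowest coverage listed is 1 read in the uninjured and 4 dpi libraries and 5 reads in the 4 morpholino libraries, so the files were filtered differently. Sample numbers in the labels fall into 2 runs, 1 with the uninjured and 4 dpi libraries and 1 with the morpholino libraries, which are called the first and the morpholino series here. The uninjured and 2 dpi fish carry the gfap:gfp reporter and the 4 dpi fish the 1016 tub1a:gfp reporter.

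Methylated and unmethylated reads of the 2 strands of each CpG were summed, and a CpG entered a comparison when each library compared had at least 10 reads there. Mean methylation was taken over those CpGs with equal weight per CpG and compared by a two-sided exact permutation test, which cannot go below p = 0.333 with 2 libraries against 2. Equal weights keep deep fragments from setting the mean. Means weighted by reads also depend on how the reads of each library fall over CpGs, so they can differ without a change at any CpG. For each CpG with a pooled level of 5 to 95% a binomial logistic model of methylated and unmethylated reads on group was fitted to the 4 libraries. Overdispersion was estimated per CpG with a floor of 1 and moderated across CpGs with the empirical Bayes function of limma 3.58.1, with a trend on log coverage and a prior estimated from CpGs with pooled levels of 10 to 90%. A quasi-likelihood F-test gave p-values, which were adjusted by Benjamini and Hochberg's method over the CpGs of the comparison. A CpG was called when the adjusted p was under 0.05 and the group levels differed by at least 25 percentage points. Reads were also summed over non-overlapping tiles of 1000 bp with at least 3 such CpGs, and tiles were tested and called alike. The labels do not say that replicate libraries came from separate animals, so p-values measure the spread between these libraries only, and PCR reads without molecular identifiers are not independent molecules.

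The test was checked on data simulated from the real levels, coverage and overdispersion. Among simulated CpGs with a true difference of 40 points it called 74% for 4 dpi against uninjured glia, 64% for 2 dpi control against uninjured glia, 54% for the knockdown comparison and 70% for 4 dpi against 2 dpi. With no change simulated it called 0 CpGs and 0 tiles in each comparison. For true differences of 25 points the recovered share of CpGs was 26%, 18%, 6% and 16% in the same order. Only 50 units per size of difference were changed, all drawn from units with intermediate pooled levels. Recovery with many changed units or at low and high levels was not simulated.

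No genome or annotation in the Zv9 build was used here, and the gene table at hand is in another build. Promoters and gene lists planned before the data were examined were therefore not tested, and regions are named by their Zv9 coordinates, counted from 1. The rule for naming, also fixed before the data were examined, took the 6 called tiles with the largest difference in each direction in which both libraries of 1 group lay above both of the other. For the knockdown comparison, which had no called tile, all called CpGs are named.

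Alternatives fixed before the data were examined were a minimum of 20 reads, removal of the deepest CpGs, strands kept apart, no overdispersion, edgeR 4.0.16 on methylated and unmethylated counts, thinning to 10 reads, 1 fit over all 8 libraries, no filter on the pooled level, a minimum difference of 10 points, at least 5 CpGs per tile, and leaving out each library in turn. After the data were seen, 3 more were added. The first left out C calls preceded by a C on the same strand, which include every MspI fragment end. The second required 5 reads per strand in every library, and the third required 10 reads per strand in all 4 libraries together with the first. A C was taken to follow a C when the neighbouring base carried a CHG call in any library. Tables were handled with R 4.3.3, Python 3.11.15 and pandas 2.3.3.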

Results

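DNA methylation was profiled in Müller glia sorted from uninjured zebrafish retinas and from retinas that had been injured with a needle, when Müller glia dedifferentiate and divide as progenitors. The 4 groups held 2 libraries each: uninjured glia, progenitors 4 dpi (12 lesions per eye), and progenitors 2 dpi that had received either a control morpholino or an apobec2a,2b morpholino (6 injections of 0.7 µL at 0.25 mM and 6 additional lesions per eye). Apobec2 proteins belong to the AID/APOBEC family, whose best-known members are cytidine deaminases. Depth differed between groups. The uninjured libraries held 30506981 and 31055638 CpG read calls and the 4 dpi libraries 41396255 and 35059446. The control morpholino libraries held 12602711 and 21556871, and the apobec2a,2b libraries 5857290 and 6840647. All 8 libraries covered 146621 CpGs with at least 10 reads, at a median of 105 and 100 reads in uninjured glia, 71 and 69 at 4 dpi, 45 and 79 with the control morpholino, and 24 and 29 with the apobec2a,2b morpholino.

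Over these shared CpGs the methylome of Müller glia was bimodal, and its mean differed by under 2 points between groups with equal weight per CpG. The mean methylation level was 63.7% ± 0.19 (SD, n = 2) in uninjured glia and 64.1% ± 0.22 at 4 dpi. At 2 dpi it was 62.2% ± 0.083 with the control morpholino and 62.5% ± 0.018 with the apobec2a,2b morpholino. Weighted by reads, the means were 56.6% ± 0.88, 58.8% ± 0.49, 51.1% ± 0.82 and 53.2% ± 0.21 in the same order. CpGs with a level above 80% made up 59.3% ± 0.18 of the sites in uninjured glia, 59.3% ± 0.085 at 4 dpi, 56.6% ± 0.096 in 2 dpi controls and 56.6% ± 0.31 in 2 dpi knockdown cells. Partly methylated CpGs, with levels of 20 to 80%, were least frequent in uninjured glia, at 11.6% ± 0.0039 of sites. Their share was 12.8% ± 0.15 at 4 dpi, 13.3% ± 0.15 with the control morpholino and 13.5% ± 0.43 with the apobec2a,2b morpholino. Without C calls preceded by a C these shares were 11.5%, 12.6%, 12.1% and 12.4%. None of these shares was taken at equal depth. Uninjured glia had the highest median of reads per CpG, so depth and group cannot be told apart in this order.

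**Figure D1:**
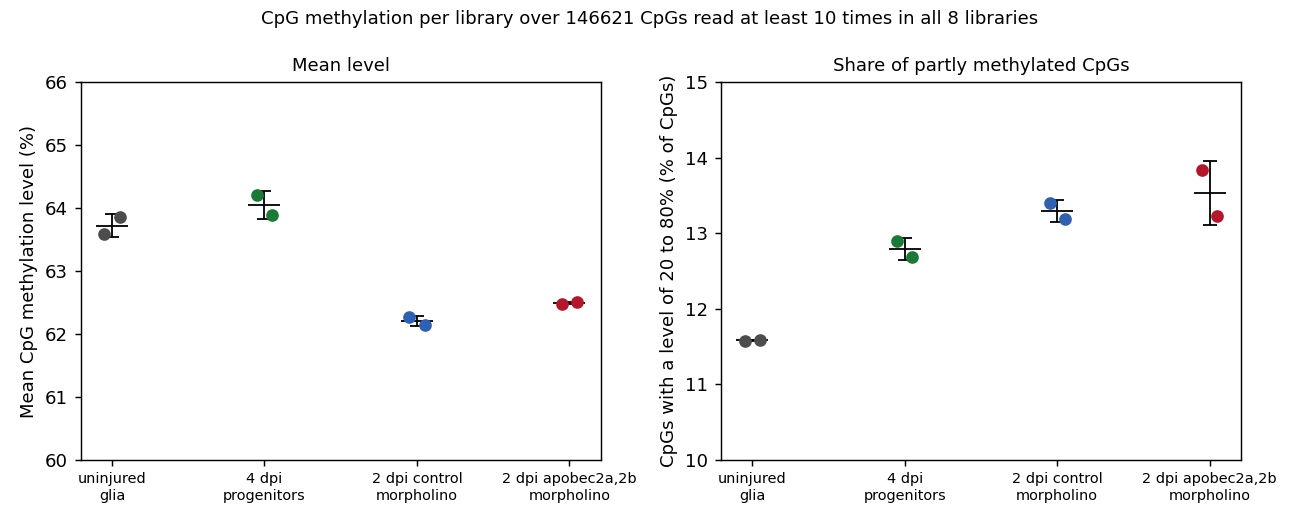
Mean CpG methylation level (left, %) and share of CpGs with a level of 20 to 80% (right, % of CpGs) in each of the 8 libraries, over 146621 CpGs with at least 10 reads in every library. Points are libraries, the bars are group means with SD (n = 2), and the vertical axes do not start at 0. The 2 dpi control libraries averaged 62.2% and the uninjured libraries 63.7%.

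The comparison of 4 dpi progenitors with uninjured glia asks how methylation differs between dividing progenitors and quiescent Müller glia. Single CpGs differed in both directions in nearly equal numbers. Of 133951 CpGs tested, 2896 had higher and 2398 lower methylation at 4 dpi, with median differences of 35.1 and -35.7 percentage points. Among 27667 tiles of 1 kb, 121 were higher and 69 lower. The mean level over 369940 CpGs was 74.2% ± 0.23 at 4 dpi and 73.9% ± 0.21 in uninjured glia (n = 2 each, exact permutation p = 0.667). Weighted by reads it was 67.9% and 66.1%, a difference of 1.87 points with both 4 dpi libraries higher (exact permutation p = 0.333, the smallest possible), and over the 146621 CpGs covered in all 8 libraries the difference was 0.336 points with the same p.

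The region with the largest gain at 4 dpi lay on chromosome 7 at 130001 to 131000 (Zv9, as for all coordinates), where methylation was 20.5% ± 0.56 in uninjured glia and 84.2% ± 10.98 at 4 dpi (SD, n = 2). A tile on chromosome 25 at 8788001 to 8789000 rose from 45.3% ± 5.9 to 99.6% ± 0.60, and 1 on chromosome 20 at 54112001 to 54113000 from 43.5% ± 14.4 to 96.4% ± 1.3. The tiles on chromosome 11 at 43997001 to 43998000 and on chromosome 19 at 35683001 to 35684000 rose from 30.7% ± 6.2 to 83.1% ± 5.1 and from 49.2% ± 4.8 to 96.0% ± 2.8. On chromosome 13 at 246001 to 247000, with 10 CpGs and 2567 reads, the level rose from 50.5% ± 0.34 to 96.8% ± 1.6. The largest loss was on chromosome 3 at 5282001 to 5283000, from 95.5% ± 3.5 to 32.3% ± 10.9. A second tile on chromosome 3, at 22157001 to 22158000, fell from 94.2% ± 3.8 to 35.0% ± 2.7. The tile on chromosome 12 at 9937001 to 9938000 fell from 80.5% ± 5.0 to 29.2% ± 3.6, and that on chromosome 1 at 10960001 to 10961000 from 83.4% ± 4.2 to 39.5% ± 6.1. Smaller losses stood on chromosome 3 at 60557001 to 60558000 (76.4% ± 2.7 to 34.9% ± 2.2) and on chromosome 14 at 30678001 to 30679000 (99.2% ± 1.1 to 58.7% ± 1.3). Adjusted p-values of these 12 tiles ran from 0.0133 to 0.0264, on 261 to 2567 reads over the 4 libraries.

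At the CpGs that differed at 4 dpi, the 2 dpi libraries lay close to uninjured glia. Of the CpGs higher at 4 dpi, 868 were covered in all 8 libraries. Their median level was 35.7% ± 1.9 in uninjured glia, 72.6% ± 2.7 at 4 dpi, 40.3% ± 1.1 in 2 dpi controls and 40.0% ± 0.0 in 2 dpi knockdown cells (SD of library medians, n = 2). At 795 CpGs lower at 4 dpi the medians were 82.3% ± 1.0, 42.5% ± 2.8, 78.4% ± 0.83 and 79.6% ± 1.9 in the same order. The 4 dpi fish carried another reporter line than all the others, and cells were sorted by the GFP of the reporter. Line, the cells that its reporter selects and time after injury therefore cannot be told apart in this comparison. Without any 1 of the 4 libraries, whether 4 dpi or uninjured, 0 tiles passed. The 12 named tiles kept their direction with adjusted p-values of 0.0794 to 0.188, and the difference on chromosome 7 was 55.9 to 71.5 points in place of 63.7. In the same runs 0 to 452 CpGs passed, or 3523 to 4853 CpGs with the prior for the overdispersion kept from all 4 libraries.

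The comparison of 2 dpi control morpholino progenitors with uninjured glia asks what changes early after injury. Most of the CpGs that differed had lower methylation at 2 dpi. Of 84056 CpGs tested, 1112 were higher and 4984 lower at 2 dpi, with median differences of 38.0 and -40.3 percentage points, and of 17540 tiles 26 were higher and 596 lower. Without C calls preceded by a C on the same strand, these counts were 548 and 1618 of 60126 CpGs and 13 and 239 of 12303 tiles. The mean level over 242047 CpGs was 66.1% ± 0.094 at 2 dpi and 67.7% ± 0.21 in uninjured glia, with both 2 dpi libraries lower than both uninjured libraries (n = 2 each, exact permutation p = 0.333, the smallest possible). The difference was -1.55 points, and -6.42 points when weighted by reads (54.2% and 60.6%). These means include C calls preceded by a C, among them the fragment ends described below. The read-weighted difference also depends on how the reads of each library fall over CpGs.

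The largest loss was on chromosome 4 at 29466001 to 29467000, where methylation was 97.9% ± 2.4 in uninjured glia and 30.0% ± 1.4 at 2 dpi (SD, n = 2). On chromosome 7 at 70634001 to 70635000 it fell from 94.1% ± 2.8 to 31.5% ± 4.8, and on chromosome 18 at 39836001 to 39837000 from 76.6% ± 4.0 to 14.8% ± 1.3. The tiles on chromosome 6 at 12523001 to 12524000 and chromosome 8 at 11211001 to 11212000 fell from 98.4% ± 2.3 to 37.9% ± 5.9 and from 76.6% ± 0.58 to 17.2% ± 0.69. On chromosome 9 at 33417001 to 33418000 the level fell from 85.0% ± 3.9 to 26.2% ± 25.9, with a wide spread between the 2 dpi libraries. The largest gain was on chromosome 22 at 31068001 to 31069000, from 15.6% ± 11.1 to 59.6% ± 13.3. Methylation also rose on chromosome 10 at 40983001 to 40984000 (42.7% ± 1.7 to 86.4% ± 6.6), chromosome 5 at 36959001 to 36960000 (57.7% ± 13.4 to 97.0% ± 1.9) and chromosome 17 at 9801001 to 9802000 (18.1% ± 0.66 to 53.7% ± 4.6). The tiles on chromosome 6 at 52246001 to 52247000 and chromosome 1 at 39395001 to 39396000 rose from 48.8% ± 3.5 to 83.4% ± 2.4 and from 59.7% ± 1.8 to 92.1% ± 0.35. Adjusted p-values of these 12 tiles ran from 0.000871 to 0.0178, on 232 to 3418 reads. Without uninjured replicate 2 the tiles on chromosome 22 (adjusted p 0.0777, 36.1 points) and chromosome 9 (0.0845, -55.99 points) were no longer called, nor was that on chromosome 9 without uninjured replicate 1 (0.0702, -61.6 points). The other named tiles stayed called without any 1 library.

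Only 5 of these 12 tiles keep 3 CpGs once C calls preceded by a C are left out, and each of the 5 was called again. They are the tiles on chromosomes 7, 18 and 9 among the losses and on chromosomes 5 and 17 among the gains. On chromosome 18 the difference was then -60.5 points and on chromosome 7 it was -50.01 points.

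Some MspI fragment ends read differently in the morpholino series. When the ends are repaired, the second C of the CCGG site is filled in with an unmethylated C, which carries no methylation of the genome. Read ratios alone did not separate the series. Over 48051 CpG cytosines that follow a C, all with at least 10 reads of that first C in every library, the second C had under 20% of the reads of the first at 34.3% ± 0.55 of positions in uninjured glia, 30.6% ± 0.31 at 4 dpi, 29.4% ± 0.047 in 2 dpi controls and 31.6% ± 0.097 in knockdown libraries (SD, n = 2). Methylation was then compared at ends chosen for a low ratio in 1 series only. At 1387 ends with a ratio under 20% in every library of the first series and at least 10 reads of the second C in every morpholino library and of the opposite strand in all 8, the second C read as methylated in 6.40% ± 0.47 of control and 4.22% ± 0.19 of knockdown reads. The other strand of the same CpGs was methylated at 61.0% ± 0.66 and 62.1% ± 1.3, against 60.2% ± 0.27 in uninjured glia and 61.6% ± 0.24 at 4 dpi. At 367 ends chosen the other way round, the second C was methylated at 46.9% ± 0.73 in uninjured glia and 51.2% ± 0.27 at 4 dpi, and the other strand at 42.6% ± 1.3 and 44.0% ± 0.54. Of CpGs with C calls preceded by a C, 8.27% were called lower at 2 dpi and 1.47% higher. Of the others, 3.39% were called lower and 1.16% higher.

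**Figure D2:**
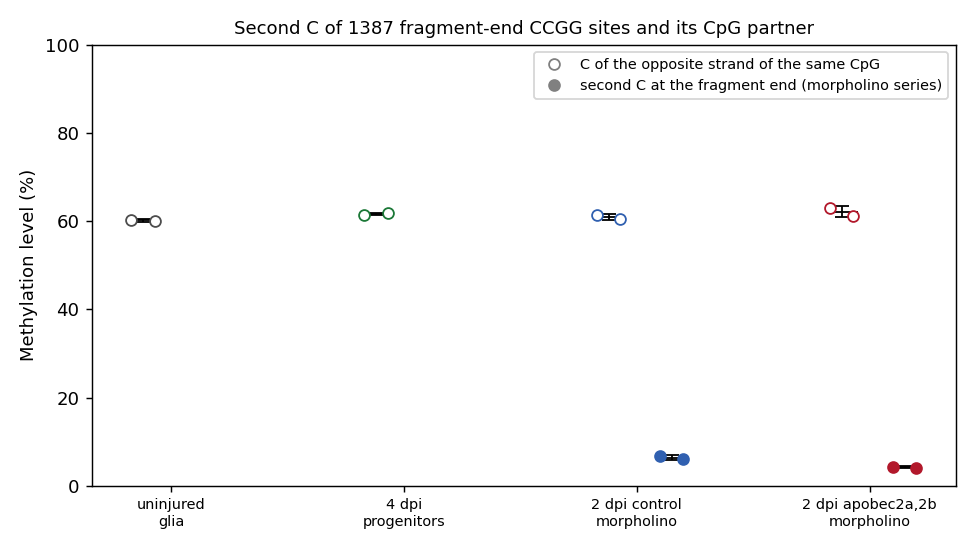
Methylation level (%) at 1387 CCGG sites at fragment ends in each library, for the second C at the fragment end (filled points, morpholino series only, since the ends were chosen for few such reads in the first series) and for the C on the opposite strand of the same CpG (open points). Black bars are group means with SD (n = 2). Fragment-end cytosines averaged 6.40% and 4.22% and their opposite strands 60.2% to 62.1%.

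At 3198 CpGs lower at 2 dpi and covered in all 8 libraries, the median level was 94.0% ± 0.26 in uninjured glia, 93.0% ± 0.0082 at 4 dpi, 46.0% ± 0.28 in 2 dpi controls and 48.5% ± 0.18 in knockdown cells. At 541 CpGs higher at 2 dpi it was 44.99% ± 0.35, 56.5% ± 0.96, 87.5% ± 0.0 and 82.3% ± 1.5. Of all 4984 lower calls, 72.6% held C calls preceded by a C, so filled-in ends may contribute to the low levels in both morpholino groups. Medians over CpGs without such C calls are given below with the knockdown comparison. Both 2 dpi groups come from the morpholino series and neither other group does. Time after injury, morpholino electroporation and library series therefore cannot be told apart. Without any 1 of the 4 libraries 534 to 865 tiles passed but 0 CpGs, with a weaker prior for the overdispersion. With the prior of all 4 libraries kept, 3898 to 6035 CpGs passed.

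**Figure D3:**
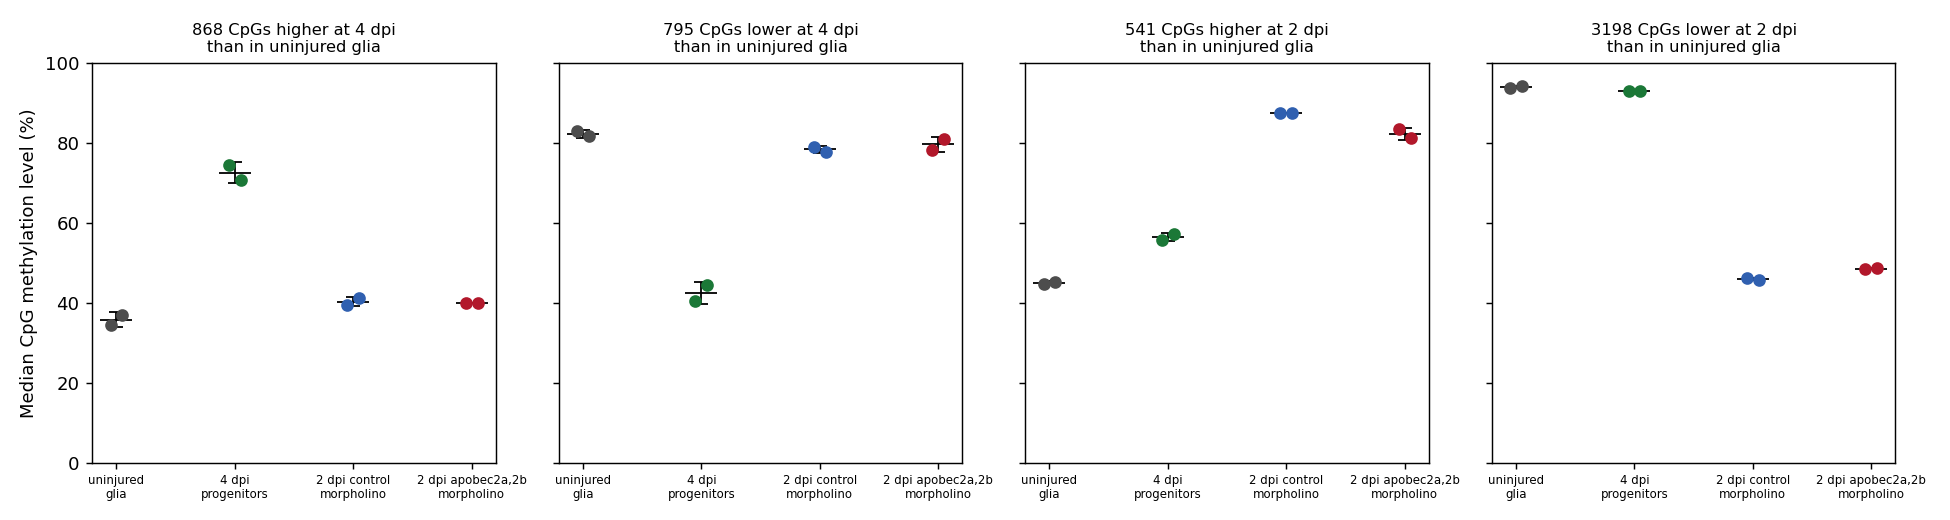
Median CpG methylation level (%) in each library at CpGs called higher or lower at 4 dpi (2 left panels) or at 2 dpi (2 right panels) than in uninjured glia, over CpGs with at least 10 reads in all 8 libraries. Points are libraries and bars are group means with SD (n = 2). The groups used for each call were chosen to differ, whereas the other groups took no part in it. At CpGs lower at 2 dpi the 4 dpi libraries had a median of 93.0% and the knockdown libraries 48.5%. CpGs with C calls preceded by a C are included, and they made up 72.6% of all lower calls at 2 dpi.

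The knockdown comparison asks whether apobec2a,2b morpholinos alter methylation of 2 dpi progenitors. Few CpGs differed between knockdown and control cells: 5 were higher and 3 lower of 52198 tested, and 0 of 11380 tiles passed in the limma-moderated test. At an unadjusted p under 0.05 there were 3057 CpGs and 695 tiles, or 5.86% and 6.11% of those tested, and edgeR called 0 CpGs and 0 tiles. A mixed split of the same libraries, with knockdown replicate 1 and control replicate 2 against the other 2, gave 4 called CpGs against the 8 of the real grouping, and the other mixed split gave 0. Mean methylation over 155721 CpGs was 63.5% ± 0.0090 with the apobec2a,2b morpholino and 63.2% ± 0.083 with the control morpholino (n = 2 each, exact permutation p = 0.333, the smallest possible). The difference was 0.272 points, and both knockdown libraries lay above both controls. Weighted by reads it was 2.08 points (54.4% and 52.3%).

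The CpG with the largest gain in knockdown cells was on chromosome 18 at 33430413, with 31.5% ± 15.3 in controls and 95.6% ± 6.2 in knockdown cells (SD, n = 2). The CpG on chromosome 24 at 25573866 rose from 48.8% ± 1.7 to 100% ± 0.0, and that on chromosome 11 at 44977854 from 36.9% ± 11.7 to 82.5% ± 8.2. Gains from 3.65% ± 2.0 to 48.3% ± 2.4 and from 0.0% ± 0.0 to 36.2% ± 4.1 were found on chromosome 5 at 12227879 and chromosome 23 at 4157322. The 3 losses were on chromosome 20 at 55777116 (68.5% ± 3.9 to 22.0% ± 1.4), chromosome 18 at 28951955 (78.4% ± 0.0 to 39.6% ± 4.9) and chromosome 23 at 4944950 (98.4% ± 2.2 to 63.5% ± 11.2). Each of these 8 CpGs had 106 to 375 reads over the 4 libraries, and adjusted p-values ran from 0.0172 to 0.0468. Without any 1 of the 4 libraries 0 CpGs passed, or 0 to 13 with the prior of all 4 kept. In simulations of this comparison, 54% of CpGs with a true difference of 40 points and 6% of those with 25 points were recovered, against 100% and 52% of tiles. With these reads, 2 libraries per group and the 25-point minimum, most simulated CpGs with a true difference of 25 points were therefore not called. This holds for few changed CpGs at intermediate levels, the only setting simulated.

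At CpGs lower in 1 of the 2 morpholino groups than in uninjured glia, the other morpholino group lay closer to that group than to uninjured glia. Over CpGs covered in all 8 libraries and without C calls preceded by a C, 774 were lower in controls than in uninjured glia. Their median level was 82.6% ± 0.024 in uninjured glia, 79.4% ± 0.88 at 4 dpi, 40.9% ± 1.3 in controls and 51.0% ± 1.4 in knockdown cells (SD of library medians, n = 2). When CpGs were instead chosen as lower in knockdown cells than in uninjured glia, 338 passed, with medians of 95.1% ± 0.0072, 93.0% ± 0.87, 51.8% ± 0.47 and 46.2% ± 0.70 in the same order. In each case the group used for the choice had the lower median. Both lists shared 229 CpGs, out of 757 and 336 among CpGs tested in both, where independent lists would share 8.20. Unchanged groups simulated 20 times against the same uninjured libraries gave 0 lower calls in either comparison, so they hold no overlap to set beside the 229. Part of the overlap may come from the shared uninjured libraries, as 2 libraries cannot be split. Both morpholino groups also share time after injury, electroporation and library series, and uninjured glia share none of these. The closeness and the overlap therefore cannot be assigned to any 1 of them.

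The comparison of 4 dpi with 2 dpi control progenitors asks how the 2 stages after injury differ. Here methylation was mostly higher at the later time. Of 92428 CpGs 8472 were higher and 1939 lower at 4 dpi, with median differences of 38.3 and -38.2 points, and of 18728 tiles 1005 were higher and 71 lower. Without C calls preceded by a C the counts were 4388 and 1082 of 66679 CpGs and 561 and 46 of 13218 tiles. Mean methylation over 242826 CpGs was 67.6% ± 0.23 at 4 dpi and 65.6% ± 0.086 at 2 dpi, with both 4 dpi libraries above both 2 dpi libraries (n = 2 each, exact permutation p = 0.333, the smallest possible). The difference was 2.00 points, and 7.68 points when weighted by reads. C calls preceded by a C are included in these means.

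The tile with the largest difference, on chromosome 7 at 67778001 to 67779000, had 97.3% ± 2.8 methylation at 4 dpi and 3.22% ± 1.2 at 2 dpi (SD, n = 2). It was followed by tiles on chromosome 4 at 9777001 to 9778000 (92.7% ± 0.23 and 12.6% ± 4.0) and on chromosome 19 at 5732001 to 5733000 (92.6% ± 5.0 and 14.3% ± 6.1). The tile on chromosome 8 at 11211001 to 11212000, also lower at 2 dpi than in uninjured glia, had 89.3% ± 4.6 at 4 dpi and 17.2% ± 0.69 at 2 dpi. On chromosome 17 at 3210001 to 3211000 the levels were 77.5% ± 1.9 and 6.58% ± 5.7. The tile on chromosome 13 at 246001 to 247000, also higher at 4 dpi than in uninjured glia, had 96.8% ± 1.6 and 25.9% ± 17.1. Lower levels at 4 dpi than at 2 dpi were largest on chromosome 3, at 22157001 to 22158000 (35.0% ± 2.7 and 95.4% ± 4.4) and at 60557001 to 60558000 (34.9% ± 2.2 and 89.7% ± 5.0). Further tiles lower at 4 dpi lay on chromosome 19 at 35715001 to 35716000 (38.8% ± 7.2 and 86.1% ± 9.3) and at 7508001 to 7509000 (48.7% ± 6.3 and 93.3% ± 3.6). The others lay on chromosome 1 at 39395001 to 39396000 (47.3% ± 11.5 and 92.1% ± 0.35) and chromosome 14 at 45201001 to 45202000 (41.1% ± 13.2 and 84.4% ± 3.0). Adjusted p-values of these 12 tiles ran from 0.000302 to 0.0014. Of the 12, 7 keep 3 CpGs without C calls preceded by a C, and each of the 7 was called again. Reporter line, with the cells that its GFP selects, library series, morpholino treatment and time all differ between these groups and cannot be told apart. Leaving out any 1 of the 4 libraries gave 970 to 1441 tiles and 0 CpGs, and 6844 to 10550 CpGs with the prior of all 4 libraries kept.

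**Figure D4:**
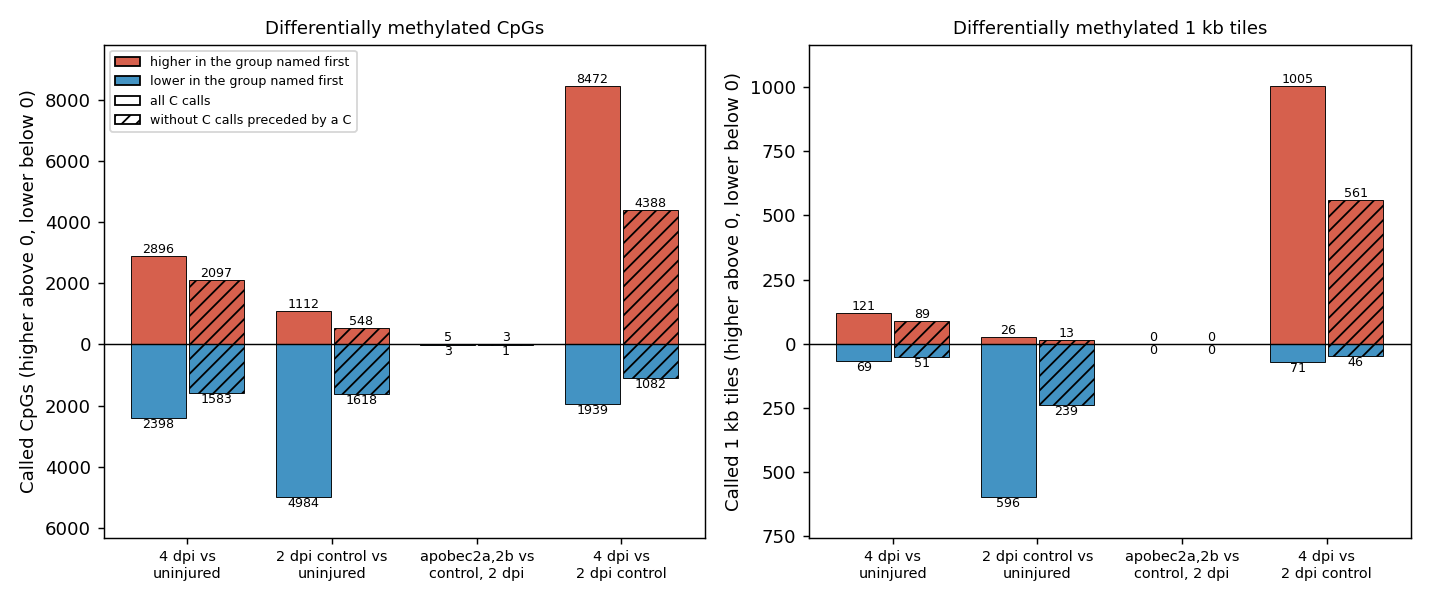
Number of differentially methylated CpGs (left) and 1 kb tiles (right) in each comparison, higher in the group named first above 0 and lower below 0, with all C calls (plain bars) and without C calls preceded by a C (hatched bars). At 2 dpi against uninjured glia 4984 CpGs were lower with all C calls and 1618 without those calls.

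Tiles that differed from uninjured glia at 2 dpi and at 4 dpi were largely separate. Of 15484 tiles tested in both comparisons, 79 were higher at 4 dpi and 24 at 2 dpi, and 3 were higher in both, where independent lists would share 0.122. Lower methylation was found in 34 tiles at 4 dpi, 415 at 2 dpi and 5 in both, where independent lists would share 0.911. A further 7 tiles were higher at 4 dpi and lower at 2 dpi. Across tiles, which are not independent replicates, the differences from uninjured glia had a correlation of 0.0656 and a covariance of 4.04. Unchanged groups simulated against 1 shared uninjured group, itself redrawn from the uninjured levels, gave 0.454 and 5.66. Part of the overlap of calls may come from the shared uninjured libraries, as 2 libraries cannot be split.

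Cytosines outside CpG were almost wholly converted. Unconverted reads made up 0.875% ± 0.028 of CHG reads in uninjured glia, 0.826% ± 0.0039 at 4 dpi, 0.784% ± 0.010 in 2 dpi controls and 0.811% ± 0.014 in knockdown cells (SD, n = 2). In CHH context the shares were 0.661% ± 0.027, 0.673% ± 0.011, 0.656% ± 0.0019 and 0.818% ± 0.014. The difference between knockdown and control in CHH was 0.162 points, larger than the spread between replicates (n = 2 each, exact permutation p = 0.333, the smallest possible). On the mitochondrial genome alone it was 0.0168 points, within that spread (exact permutation p = 0.667). These shares bound the failure of bisulfite conversion from above.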

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

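The tests with C calls left out, the bisulfite conversion test and the choice to count non-CpG cytosines methylated in 1 series were made only after the results were seen. The strand test was set aside after its value was seen, and the tests on alleles at partial frequency, on the side taken by 2 dpi glia and on tiles without 1 CpG were added after the first allele ratio was seen.

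The 4 dpi and 2 dpi groups differed from each other when tested directly, with 1005 tiles of 1 kb higher and 71 lower at 4 dpi. Against uninjured glia, tile calls were mostly higher at 4 dpi (121 of 190) and mostly lower at 2 dpi (596 of 622).

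CpGs that differed between 2 dpi controls and uninjured glia were mostly lower at 2 dpi (4984 of 6096). Incomplete conversion of the uninjured libraries is excluded, as their CHH share differed by 0.00445 points. The 5-read minimum of the morpholino files is excluded too. With it applied throughout, the number of lower CpG calls was 99.4% of that reported. Filled-in cytosines at fragment ends remain a candidate cause of the 3616 lower calls with C calls preceded by a C: without those calls the median fall at 1662 of them was 2.90 points (quartiles -0.720 and 29.0) in place of 42.0. They do not account for the 1368 lower calls without such C calls, which outnumber 470 higher calls. At 589 lower calls read on both strands, the strand with the smaller fall had a median fall of 20.2 points (quartiles 1.14 and 28.2). This decides nothing, since at 196 of them the C of either strand follows a C and both can be filled in. Of those 1368 lower calls, 1202 had a covered neighbour within 50 bp. Over 3304 pairs of call and neighbour, the neighbours fell by a median of 14.1 points (quartiles 0.696 and 31.7). Single-base variants that each alter 1 CpG are thereby argued against as the cause of all these calls. The share of calls they could explain was not counted, as clustered calls enter several pairs. A difference between the library series cannot be told apart from injury or electroporation. At the lower calls the knockdown libraries lay -39.8 points from the 4 dpi libraries (median, quartiles -49.6 and -24.4), and both series and time separate them.

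The CpG changes at 4 dpi against uninjured glia were mostly single CpGs. Other CpGs within 50 bp of a called CpG differed by a median of only 1.16 points in the direction of the call. The quartiles were -1.30 and 9.67 over 19944 pairs of call and neighbour, in which clustered calls enter several pairs. Of 5294 calls, 5018 had a covered neighbour, and at 64.0% of these the neighbours differed by a mean of under 5 points. Single-base variants that each alter 1 CpG would give such a low median. Alleles that create a CpG were counted to look for an excess of variants between the 2 reporter lines. The 2 dpi comparison used as the reference lies within the gfap:gfp line but crosses the 2 library series. Its counts may hold differences between the series, so ratios under 1 cannot exclude an excess between the lines. The rate of non-CpG cytosines methylated in 1 group alone was 0.169 times that of the 2 dpi comparison within the gfap:gfp line (49 of 1768527 and 145 of 884210 positions, 95% interval 0.120 to 0.235, exact for Poisson counts and covering counting error only). Counting only positions methylated in uninjured glia, which leaves out the 118 methylated in the morpholino series, the ratio was 0.444 (0.245 to 0.80). With alleles at partial frequency, 61 positions against 4 dpi and 125 against 2 dpi of 833219 gave 0.488 (0.353 to 0.668). The 2 dpi controls lay closer to uninjured glia than to 4 dpi at 54.1% of those 61 positions (exact binomial 95% interval 40.8 to 66.9), which leaves undecided whether such alleles follow the line. For the single CpG calls as a whole, variants, the cells selected by each reporter and a change at 4 dpi cannot be told apart. At most calls, though not all, the neighbours are as variants would leave them. The allele counts cannot decide, as their references within the gfap:gfp line differ. Between the lines, 49 of 1768527 positions were methylated in 1 group alone. The 2 dpi comparison across the library series gave 145 of 884210. Knockdown against control, within the morpholino series, gave 0 of 580549. For 4 dpi against 2 dpi controls, which crosses both line and series, the count was 205 of 896533. At the calls, the 2 dpi libraries stayed near the uninjured level.

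Most called tiles at 4 dpi did not rest on 1 CpG. Without the CpG that differed most, the 190 tiles still differed by a median of 25.8 points in the direction of the call (quartiles 21.9 and 30.6), in place of 29.9, and 166 of them by 10 points or more. For the 142 tiles of 3 to 5 CpGs the median was 25.3 points. A single variant CpG is thereby argued against for most tiles, while several variants in 1 tile, another effect of the line and a change at 4 dpi remain open, as line and time are not separated here.

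Few CpGs changed with the apobec2a,2b morpholino. Low depth alone would not hide changes like those against uninjured glia. With the uninjured libraries thinned to the reads of the knockdown libraries, 2 dpi control against uninjured glia still gave 3215 called CpGs (3811 unthinned). The knockdown comparison gave 4 over the same CpGs. The 3215 calls cross the library series and include C calls preceded by a C. They may thus hold differences that a comparison within the morpholino series cannot show. Smaller changes could still be missed, as 6% of simulated CpGs with a difference of 25 points were called. Weak knockdown was not tested, since these data hold no measure of the target genes.

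Reference cytosines outside CpG gave a signal in the morpholino series: 118 positions (36 CHG and 82 CHH) were methylated at 50% or more in both 2 dpi control libraries and at most 10% in both uninjured libraries, against 27 the other way. Of the 118, 92 had at least 10 reads in both 4 dpi libraries and 85 in both knockdown libraries. Their median level was 76.4% ± 0.19 in controls, 74.0% ± 1.4 in knockdown cells, and 0.0% ± 0.0 both in uninjured glia and at 4 dpi (SD of library medians, n = 2). Whether these bases are CpGs in the genomes of these fish, or follow from a difference in alignment between the series, was not tested.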

How the results depend on the processing

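The alternatives with C calls preceded by a C left out, those requiring reads on each strand in every library, and the runs with a kept prior were chosen after seeing the data. No alternative turned the direction of a difference in mean CpG methylation or of a named tile. Weighting by reads made the mean differences larger, at 1.87, -6.42, 2.08 and 7.68 points in place of 0.277, -1.55, 0.272 and 2.00 for 4 dpi against uninjured glia, 2 dpi against uninjured glia, the knockdown and 4 dpi against 2 dpi. Methylation and the spread of reads over CpGs were not separated in these weighted differences. The balance of higher and lower calls kept its direction too, except at 4 dpi against uninjured glia, where 217 CpGs were higher and 235 lower without uninjured replicate 1 and 73 and 87 without uninjured replicate 2. With the prior of all 4 libraries kept, these were 2180 and 2048, and 2605 and 2082. With that prior the balance turned in 2 other runs: 128 higher and 135 lower CpGs at 4 dpi with 10 reads, and 2 and 4 in the knockdown without control replicate 2. Promoter windows and gene lists were not run, as no annotation in the build was used. No paired analysis was possible because the labels pair no libraries across groups. Removing the deepest CpGs and requiring 5 reads per strand moved no count by over 1.5 times. Where a cause is not named, the cause was not tested.

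Called totals, higher and lower together, were 5294 CpGs and 190 tiles at 4 dpi against uninjured glia. They were 3281 CpGs and 119 tiles with 10 reads per strand and without C calls preceded by a C, and 1653 CpGs and 71 tiles with 1 fit over all 8 libraries, which tests fewer sites. A minimum difference of 10 points gave 9862 CpGs and 1308 tiles. Tiles numbered 114 with at least 20 reads, 67 with at least 5 CpGs per tile and 82 with no filter on the pooled level. At 2 dpi against uninjured glia the totals were 6096 CpGs and 622 tiles. Without C calls preceded by a C they were 2166 and 252, with 10 reads per strand as well 1774 and 215, with strands kept apart 3381 and 296, and with 1 fit over all 8 libraries 3948 and 362. Tiles numbered 366 with at least 20 reads, 145 with at least 5 CpGs and 2458 with a 10-point minimum.

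In the knockdown comparison, with 8 CpGs and 0 tiles called, there were 4 CpGs without C calls preceded by a C, 2 with strands kept apart and 3 with 1 fit over all 8 libraries. With at least 20 reads, with edgeR, with no filter on the pooled level, and with 10 reads per strand and without C calls preceded by a C there were 0 each. With no overdispersion, which ignores the spread between replicates, 371 CpGs and 14 tiles passed. For 4 dpi against 2 dpi the totals were 10411 CpGs and 1076 tiles. They were 5470 and 607 without C calls preceded by a C, 5063 and 556 with 10 reads per strand as well, 6315 and 541 with at least 20 reads, and 5962 and 568 with 1 fit over all 8 libraries. A 10-point minimum gave 15653 CpGs and 4291 tiles, and at least 5 CpGs per tile 336 tiles.

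With every CpG thinned to 10 reads, 0 CpGs and 0 tiles passed in each comparison. With the prior for overdispersion kept from full depth, 263, 231, 0 and 1754 CpGs and 0, 0, 0 and 646 tiles passed for 4 dpi against uninjured glia, 2 dpi against uninjured glia, the knockdown and 4 dpi against 2 dpi, so depth limits the CpG calls with that prior too. Leaving out 1 library in turn gave 0 to 452 CpGs and 0 to 0 tiles at 4 dpi against uninjured glia, 0 to 0 CpGs and 534 to 865 tiles at 2 dpi, 0 to 0 CpGs and tiles for the knockdown, and 0 to 0 CpGs and 970 to 1441 tiles for 4 dpi against 2 dpi. The lone library of a group was assumed to vary like the other group. Most, though not all, of the loss of CpG calls came from the weaker prior in the 3 comparisons with many calls. Most of the number of CpG calls was restored there with the prior for overdispersion kept from all 4 libraries. The tiles at 4 dpi against uninjured glia stayed at 0 with that prior.

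The share of CpGs at 20 to 80% was 10.1% in uninjured glia, 11.4% at 4 dpi, 11.9% in 2 dpi controls and 12.2% in knockdown cells with at least 20 reads, and 11.5%, 12.6%, 12.1% and 12.4% without C calls preceded by a C. On the mitochondrial genome alone, unconverted CHG reads were 0.405%, 0.405%, 0.286% and 0.284% and CHH reads 0.494%, 0.442%, 0.313% and 0.329% in the same order. Differences that turned there were CHH at 4 dpi minus uninjured (0.0119 to -0.0519 points), CHG at 4 dpi minus uninjured (-0.0483 to 9.2e-05) and CHG in knockdown minus control (0.0269 to -0.0019). The last 2 lay within the replicate spread. Tiles shared by 2 dpi and 4 dpi numbered 35 higher and 50 lower with a 10-point minimum and 0 higher and 4 lower without C calls preceded by a C. Leaving out 1 library in turn gave 0 to 3 shared higher and 0 to 7 shared lower tiles.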

Other observations

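Outside the knockdown comparison, calls were spread over all chromosomes. The called share of CpGs at 4 dpi against uninjured glia ran from 2.81% on chromosome 13 to 6.03% on chromosome 21, and at 2 dpi from 5.87% on chromosome 15 to 8.80% on chromosome 23.

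The mean chi-square per CpG between the replicate libraries of a group was 1.39 in uninjured glia, 1.18 at 4 dpi, 1.67 in 2 dpi controls and 1.48 in knockdown cells at full depth. For counting error alone it is near 1 at high depth and slightly above 1 at 10 reads. It also takes up differences between the 2 samples. Over CpGs covered in all 8 libraries and thinned to 10 reads it was 1.09, 1.07, 1.15 and 1.18. Mitochondrial CpGs read as methylated in 0.488% ± 0.0060 of reads in uninjured glia, 0.446% ± 0.011 at 4 dpi, 0.462% ± 0.075 in controls and 0.423% ± 0.042 in knockdown cells.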
